A study of Rattus norvegicus with 30 samples.

How the data were processed

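RNA was measured in primary hepatocytes of male Sprague Dawley rats. Per the labels' protocols, frozen cells from a commercial supplier were thawed, plated on collagen under a Matrigel overlay, and dosed on day 3 of culture with diisononyl phthalate (DINP), a plasticiser, or with 1% DMSO alone as the vehicle. RNA was taken 24 or 48 h later, after the cells had been viewed under a light microscope for cytotoxicity. The labels give the concentrations as 25 and 100 mM, and that unit is kept here as written, although whether mM is the intended unit could not be checked. The 30 samples make 6 groups of 5 arrays: vehicle, 25 mM and 100 mM at each time. The labels call the 5 wells of a group independent cultures. The donor animals are not given in the sources used here, so the p-values measure the spread between wells. The labels give no replicate numbers, so replicates were numbered in the order of the samples, which is that of the rounds of array numbers below.

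Biotin-labelled cRNA was hybridised to Affymetrix rat expression arrays, per the labels' protocols. The deposited values are linear signal intensities, 1 per probe set and array, made with MAS5 per the submitters' processing notes, with no version given in the sources used here. The deposited intensities had a 2% trimmed mean between 1499.93 and 1499.94 on every array, so each array had been scaled to one mean before deposit. The table held 31099 probe sets and no detection calls. For arrays, the number of arrays limits the precision, and here each group mean rests on 5.

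From these values, log2(signal + 16) was computed. A log2 difference or fold is therefore on the log2(signal + 16) scale, which understates the change of dim genes. Where the mean of one group lies below the dimmest tested mean given next, as for Acot1, Nim1k, Fabp3, Ucp2, Dnajb3, Tpcn2, Prr15l, Sned1 and others, signal above background is not shown in that group, and the difference from a brighter group is a lower limit that depends on the added constant. Where both means lie below it, no change is shown. The 57 control probe sets were dropped, leaving 31042, and probe sets whose mean log2 value over all arrays lay at or above the 40th percentile were tested. This left 18625 probe sets, the dimmest of them at a mean of 7.956. Of the 31042 probe sets, 20826 had 1 gene symbol, 436 had several and 9780 were unnamed here. Among the tested ones the numbers were 14164, 342 and 4119. Symbols came from the platform annotation, which can be old, and were updated through the Entrez ID for the 20758 probe sets whose ID was in the reference gene table of assembly GRCr8, used for names only. A gene was represented by its brightest tested probe set, which gave 10604 genes, 2730 of them with more than 1 tested probe set. Probe sets of one gene were called in opposite directions for 3 genes at 25 mM and 48 h (Atp5if1, Cldn1 and Tor1aip2) and for 2 at 100 mM and 48 h (Fkbp8 and Tor1aip2), and for 0 genes at 24 h. These names were chosen after their values were seen. Probes of closely related genes, such as those of the Cyp4a, Cyp2c, Cyp3a and Acot families, can bind each other's transcripts, so members of such families are less certain.

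Differences were tested with limma 3.58.1 in R 4.3.3, in 1 fit of all 6 groups that leaves 24 residual degrees of freedom. The fit used empirical Bayes moderation with a trend on mean signal and Benjamini-Hochberg adjustment within each comparison, with a threshold of 0.05. Errors given as ± beside a log2 difference are limma's moderated standard errors, with 5 arrays in each group. The comparisons were each dose against the vehicle of its time, the doses against each other at each time, the difference of each dose's effect between the times, and 48 against 24 h in the vehicle cultures. For the last of these, time in culture and time in vehicle pass together.

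In all, 31 gene lists (pathways of lipid, glucose, amino acid, bile acid and drug metabolism, stress responses, secreted proteins, and markers of other liver cell types) held 649 members, of which 502 matched a tested gene. The lists, designs, alternatives and the rule for named genes were fixed before the data were examined. Lists with at least 5 measured members, 29 of the 31, were tested with limma's camera at a preset correlation between genes of 0.01, and adjusted over the lists. The same test with an estimated correlation, limma's fry, quantile normalisation, and the median over a gene's probe sets were the alternatives. Beside each list the number of members past the threshold is given over all genes and adjusted over the list alone. The lymphocyte and erythroid marker lists were too small to test.

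By the rule for named genes, the text names, per comparison with the vehicle, the 8 largest rises and the 8 largest falls among called genes whose treated and vehicle arrays do not overlap, and up to 3 called members per list. It also names fixed genes of the tissue and compound class in any case, and up to 5 genes in each direction for the other comparisons. Of those fixed genes, 3 are not analysed here.

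The alternatives for the differences were a pseudocount of 1 or 64, quantile normalisation, centring each array on its median, no filter or a filter at the 60th percentile, no variance trend, array weights, only the groups compared in the fit, a stricter threshold of 0.01, a log2 difference of at least 1, and leaving out each array in turn. The sample titles number the arrays from 1 to 30 in 5 rounds of 6, each round with 1 array of every group in the same order (vehicle, 25 and 100 mM at 24 h, then at 48 h), so the place in a round cannot be separated from the group. Nothing in the labels says what a round is, and the main comparisons are unpaired, with the round tried as a block. A test of the gene lists without 1 vehicle array was added after the data were seen.

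Pairs of arrays of one group correlated at 0.95 to 0.9591 (Pearson r across probe sets, on the log2 scale; probe sets are not independent replicates). The highest value of any pair was 0.9601, and 0 pairs were identical. The first principal component held 15.1% of the variance and the second 10.1%.

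The tests were run on simulated data with the same 18625 probe sets, with 50 probe sets changed at each size. For 25 mM at 24 h, 18, 48, 86 and 98% were recovered at log2 changes of 0.25, 0.5, 1 and 2. For 100 mM at 24 h the shares were 18, 40, 86 and 100%, for 25 mM at 48 h 14, 42, 78 and 96%, and for 100 mM at 48 h 16, 52, 80 and 98%. Between the doses they were 6, 50, 80 and 96% at 24 h and 10, 48, 96 and 100% at 48 h. For the difference of effects between the times they were 4, 14, 64 and 90% at 25 mM and 10, 20, 70 and 92% at 100 mM, and for the vehicle over time 18, 38, 84 and 100%. A simulated rise of 0.3 in the 25 genes of mitochondrial β-oxidation was recovered by camera (adjusted p = 1.05e-63) with 0 of the 28 other lists called. The simulated noise was independent between genes, so this does not show how camera fares where genes vary together. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.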

Results

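Transcript levels were measured in cultured rat hepatocytes exposed to diisononyl phthalate (DINP) at 25 or 100 mM, as the labels give the dose, or to the vehicle, for 24 or 48 h, with 5 arrays in each of 6 groups. The series is part of a set of compounds studied separately in such cells at 2 doses and both times, so the comparisons ask which transcripts each dose changed at each time and whether dose or time altered the response. Of the probe sets on the array, 18625 were tested, representing 10604 genes. Differences of genes and probe sets are log2 values with limma's standard error, 5 arrays against 5, and their adjusted p-values are limma's.

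After 24 h at 25 mM, genes of fatty acid handling rose the most. Acot1, a thioesterase that splits acyl-CoA, rose by at least 6.18 ± 0.35 (log2, adjusted p = 3.41e-15). Its vehicle level, 4.40 to 6.85 (log2 signal), lay below the dimmest mean tested, 7.956, so its differences from the vehicle are lower limits that depend on the constant added before the log (5.015 with 64 and 7.145 with 1). The peroxisomal bifunctional enzyme Ehhadh rose 8.26-fold (3.05 ± 0.10, adjusted p = 1.01e-20), the pyruvate dehydrogenase kinase Pdk4 6.17-fold (2.63 ± 0.11, adjusted p = 4.03e-18) and the fatty acid ω-hydroxylase Cyp4a1 6.01-fold (2.59 ± 0.11, adjusted p = 4.77e-18). Cyp4a3, the acyl-CoA synthetase Acsl1, the kinetochore gene Spc24 and the mitochondrial carrier Ucp2 followed, with log2 rises of 2.14 ± 0.11, 2.10 ± 0.09, 2.00 ± 0.11 and 1.97 ± 0.40. The largest fall was that of Ccn2, which encodes a secreted matricellular protein, at 7-fold lower (-2.81 ± 0.10, adjusted p = 1.04e-20). Acmsd, an enzyme of tryptophan breakdown, fell by 1.63 ± 0.17 and the metalloreductase Steap4 by 1.55 ± 0.13. Sesn1 fell by 1.30 ± 0.11, Carmil1 by 1.23 ± 0.28, Cc2d2a by 1.22 ± 0.23 and the glycosyltransferase B4galt5 by 1.19 ± 0.13. Cyp7a1, the rate-limiting enzyme of bile acid synthesis, was 2.41-fold lower (-1.27 ± 0.17, adjusted p = 1.86e-06).

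**Figure D1:**
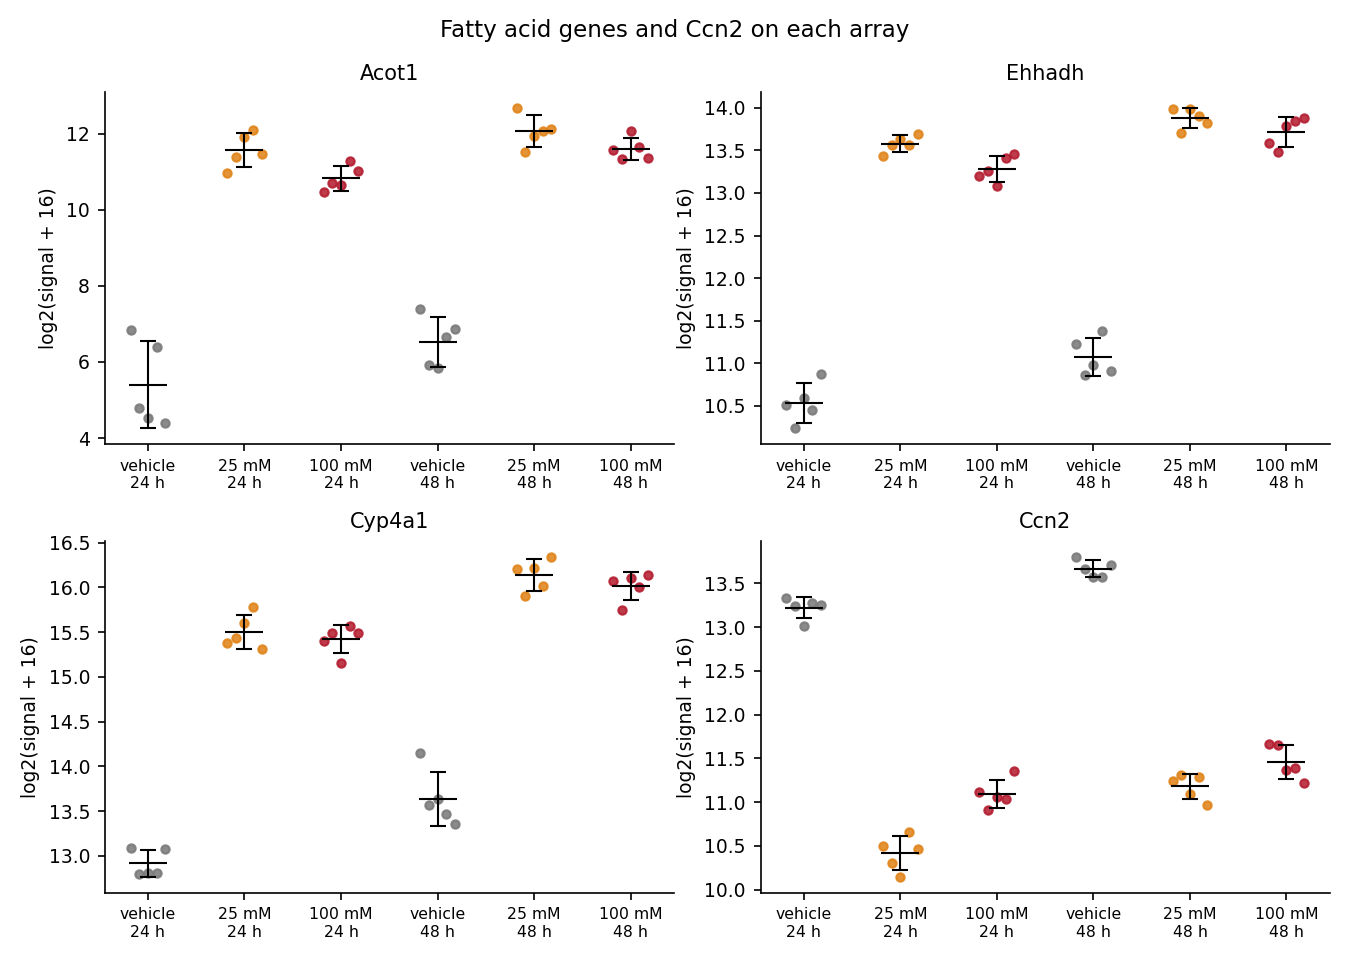
Signal of Acot1, Ehhadh, Cyp4a1 and Ccn2 on each array, as log2(signal + 16), in the 6 groups of dose (mM, as labelled) and time; points are arrays (5 per group), bars the group mean and error bars 1 SD. At 24 h Ehhadh lay between 10.23 and 10.87 on the vehicle arrays and between 13.08 and 13.69 on the treated ones, and Ccn2 lay between 13.01 and 13.33 on the vehicle arrays and between 10.15 and 10.66 at 25 mM.

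Of 20 measured genes of peroxisomal β-oxidation and peroxisome biogenesis, 19 rose at 25 mM and 24 h and 0 fell (20 rose adjusted over the list alone). Their median log2 difference was 0.94 (camera adjusted p = 1.66e-41, and adjusted p = 9.86e-07 with an estimated correlation). In the list of mitochondrial β-oxidation and ketogenesis, 23 of 25 rose and 0 fell, 23 adjusted over the list alone (median 0.86, camera adjusted p = 1.39e-47, and adjusted p = 4.95e-06 with an estimated correlation). Its members included the carnitine palmitoyltransferases Cpt1a (1.24 ± 0.14) and Cpt1b (1.62 ± 0.14), and Acot4 (1.83 ± 0.12), Ech1 (1.57 ± 0.07) and Crat (1.57 ± 0.15), which handle acyl groups in peroxisomes or mitochondria, were also among the called genes. Of 28 genes of fatty acid uptake, binding, activation and lipid droplets, 15 rose and 2 fell (19 and 2 adjusted over the list alone; median 0.50, camera adjusted p = 4.79e-19, and adjusted p = 4.95e-06 with an estimated correlation). The lipid droplet gene Hilpda rose by 1.86 ± 0.11, the lipoprotein lipase inhibitor Angptl4 by 1.72 ± 0.09 and the fatty acid-binding protein Fabp1 by 1.43 ± 0.08. The fatty acid transporter Cd36 rose by 0.51 ± 0.14 (adjusted p = 0.0149), but fell short of the threshold without DINP 25 mM 24 h replicate 5 (0.379, adjusted p = 0.0688) or vehicle 24 h replicate 4 (0.458, adjusted p = 0.0505). The pantetheinase Vnn1 and the retinal dehydrogenase Aldh1a1 each rose by 1.00 ± 0.07.

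At the same dose and time, members of other metabolic lists moved both ways. Among 23 genes of fatty acid and triglyceride synthesis, 9 rose and 10 fell (9 and 10 adjusted over the list alone; camera adjusted p = 0.873). The glycerol-3-phosphate dehydrogenases Gpd2 and Gpd1 rose by 1.54 ± 0.11 and 1.39 ± 0.09 and the acyltransferase Dgat1 by 0.85 ± 0.07, while Lpin1 fell by 0.92 ± 0.08 and the acetyl-CoA carboxylase Acaca by 0.77 ± 0.08. Of 16 genes of glucose metabolism, 7 rose and 5 fell, the same numbers adjusted over the list alone (median 0.12, camera adjusted p = 0.0215, but adjusted p = 0.333 with an estimated correlation and 0.155 after quantile normalisation). Among 8 genes of fatty acid ω-hydroxylation, 3 rose and 0 fell (3 and 1 adjusted over the list alone; median 0.08, camera adjusted p = 0.0185, but adjusted p = 0.333 with an estimated correlation). The respiratory chain list had 11 of 26 members higher and 0 lower, 19 adjusted over the list alone, with a median of 0.15 (camera adjusted p = 1.16e-08, but adjusted p = 0.155 with an estimated correlation). Its member Cyc1 rose by 0.32 ± 0.06, and Ndufb8 by 0.42 ± 0.12 (adjusted p = 0.0137), a call lost without vehicle 24 h replicate 2 (0.347, adjusted p = 0.0595). The amino acid enzymes Tat and Tdo2 fell by 0.92 ± 0.09 and 0.90 ± 0.07, the canalicular transporter Abcc2 by 0.76 ± 0.07 and the mesenchymal marker Vim by 1.01 ± 0.11. The cyclin gene Ccnd1 rose by 0.70 ± 0.13. Albumin (Alb, 0.10 ± 0.10), Fgf21 (0.38 ± 0.20) and the aryl hydrocarbon receptor target Cyp1a1 (-0.18 ± 0.11) did not pass the threshold, although Fgf21 (adjusted p = 0.0238) and Cyp1a1 (adjusted p = 0.0181) did with only the compared groups in the fit. Cyp3a23-3a1 was called at 0.17 ± 0.05 (adjusted p = 0.0313). Leaving out DINP 25 mM 24 h replicate 1 (0.140), 2 (0.156) or 4 (0.153), or vehicle 24 h replicate 1 (0.147), 2 (0.166) or 4 (0.152), ended the call, as did no filter (0.0741), no variance trend (0.0769) and only the compared groups (0.0572).

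In all, 1090 probe sets were higher and 1395 lower at 25 mM and 24 h, 13.3% of those tested, and 98 rose and 52 fell at least 2-fold. They represented 835 genes higher and 831 lower. The share of calls that were higher was 43.9%, but it was 65.2% after each array was centred on its median and 48.8% after quantile normalisation, so the balance of small rises and falls depends on the scaling. The control probe set for 5S rRNA was brighter in this group, at 2160 ± 574 signal units (SD, n = 5) against 1037 ± 180 in the vehicle (exact permutation test, 2-sided p = 0.0079, the smallest the design allows, and 0.032 adjusted over 28 tests).

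After 24 h at 100 mM, the same fatty acid genes led the rises. Acot1 rose by at least 5.43 ± 0.35 (log2, adjusted p = 1.2e-13), Ehhadh 6.73-fold (2.75 ± 0.10, adjusted p = 2.23e-19), Cyp4a1 5.68-fold (2.51 ± 0.11, adjusted p = 1.96e-17) and Pdk4 5.45-fold (2.45 ± 0.11, adjusted p = 2.13e-17). Cyp4a3 (2.06 ± 0.11), Dnajb3, which encodes a heat shock cochaperone (2.02 ± 0.36), Pkhd1l1 (1.91 ± 0.36) and the endolysosomal channel Tpcn2 (1.84 ± 0.34) completed the 8 largest rises with no overlap between arrays. Ccn2 fell by 2.13 ± 0.10, Steap4 by 1.49 ± 0.13, Acmsd by 1.37 ± 0.17 and the glycolytic regulator Pfkfb3 by 1.30 ± 0.20. Cyp7a1 fell by 1.21 ± 0.17, Rab11fip5 by 1.16 ± 0.11, Diaph3 by 1.14 ± 0.26 and Sesn1 by 1.13 ± 0.11. Further rises were those of Acsl1 (1.83 ± 0.09), Hilpda (1.66 ± 0.11), Angptl4 (1.72 ± 0.09), Fabp1 (1.28 ± 0.08), Vnn1 (1.10 ± 0.07), Cpt1a (1.09 ± 0.14), Cd36 (0.70 ± 0.14) and Ccnd1 (0.70 ± 0.13). Alb (0.03 ± 0.10), Fgf21 (0.33 ± 0.20) and Cyp1a1 (-0.27 ± 0.11) did not pass the threshold. Cyp1a1 did with only the compared groups in the fit (adjusted p = 0.000514), after quantile normalisation (0.0421) and with array weights (0.0333), and Fgf21 did with only the compared groups (0.0419). Cyp3a23-3a1 (0.14 ± 0.05, adjusted p = 0.075) passed only after median centring (0.0344), with array weights (0.0369) or without DINP 100 mM 24 h replicate 5 (0.170, adjusted p = 0.0446) or vehicle 24 h replicate 5 (0.175, adjusted p = 0.0336).

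The gene groups at 100 mM and 24 h moved as follows. Of the 20 peroxisomal genes 19 rose and 0 fell, 20 adjusted over the list alone (median 0.84, camera adjusted p = 6.45e-42, and adjusted p = 9.02e-07 with an estimated correlation). In the mitochondrial β-oxidation list 23 of 25 rose and 0 fell, 23 adjusted over the list alone (median 0.77, camera adjusted p = 3.69e-47, and adjusted p = 3.79e-06 with an estimated correlation). Of the 28 fatty acid uptake and lipid droplet genes 19 rose and 2 fell, 20 and 2 adjusted over the list alone (median 0.67, camera adjusted p = 1.74e-21, and adjusted p = 2.67e-06 with an estimated correlation). The respiratory chain list had 12 higher and 0 lower, 15 adjusted over the list alone (median 0.15, camera adjusted p = 4.18e-09, but adjusted p = 0.134 with an estimated correlation). After quantile normalisation 7 of these members were called. Of the 16 glucose genes 7 rose and 4 fell, 7 and 5 adjusted over the list alone (median 0.13, camera adjusted p = 0.0102, but adjusted p = 0.24 with an estimated correlation and 0.0973 after quantile normalisation). Of the 8 ω-hydroxylation genes 3 rose and 0 fell, and 3 adjusted over the list alone (camera adjusted p = 0.0185, but adjusted p = 0.288 with an estimated correlation). Their median was -0.00 although the test ran upwards. In fatty acid and triglyceride synthesis 7 rose and 9 fell, 10 and 9 adjusted over the list alone (camera adjusted p = 0.791).

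At 100 mM and 24 h, 1033 probe sets were higher and 1255 lower, 12.3% of those tested, and 78 rose and 34 fell at least 2-fold. These were 800 genes higher and 744 lower. The share that was higher was 45.1%, against 70.8% after median centring and 51% after quantile normalisation. The 5S rRNA control lay at 2143 ± 461 signal units (SD, n = 5) against 1037 ± 180 in the vehicle (exact permutation test, 2-sided p = 0.0079, adjusted 0.032). The poly-A spike controls, RNAs added to the sample, were 0.192 log2 units brighter (exact permutation test, adjusted p = 0.032, n = 5).

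**Figure D2:**
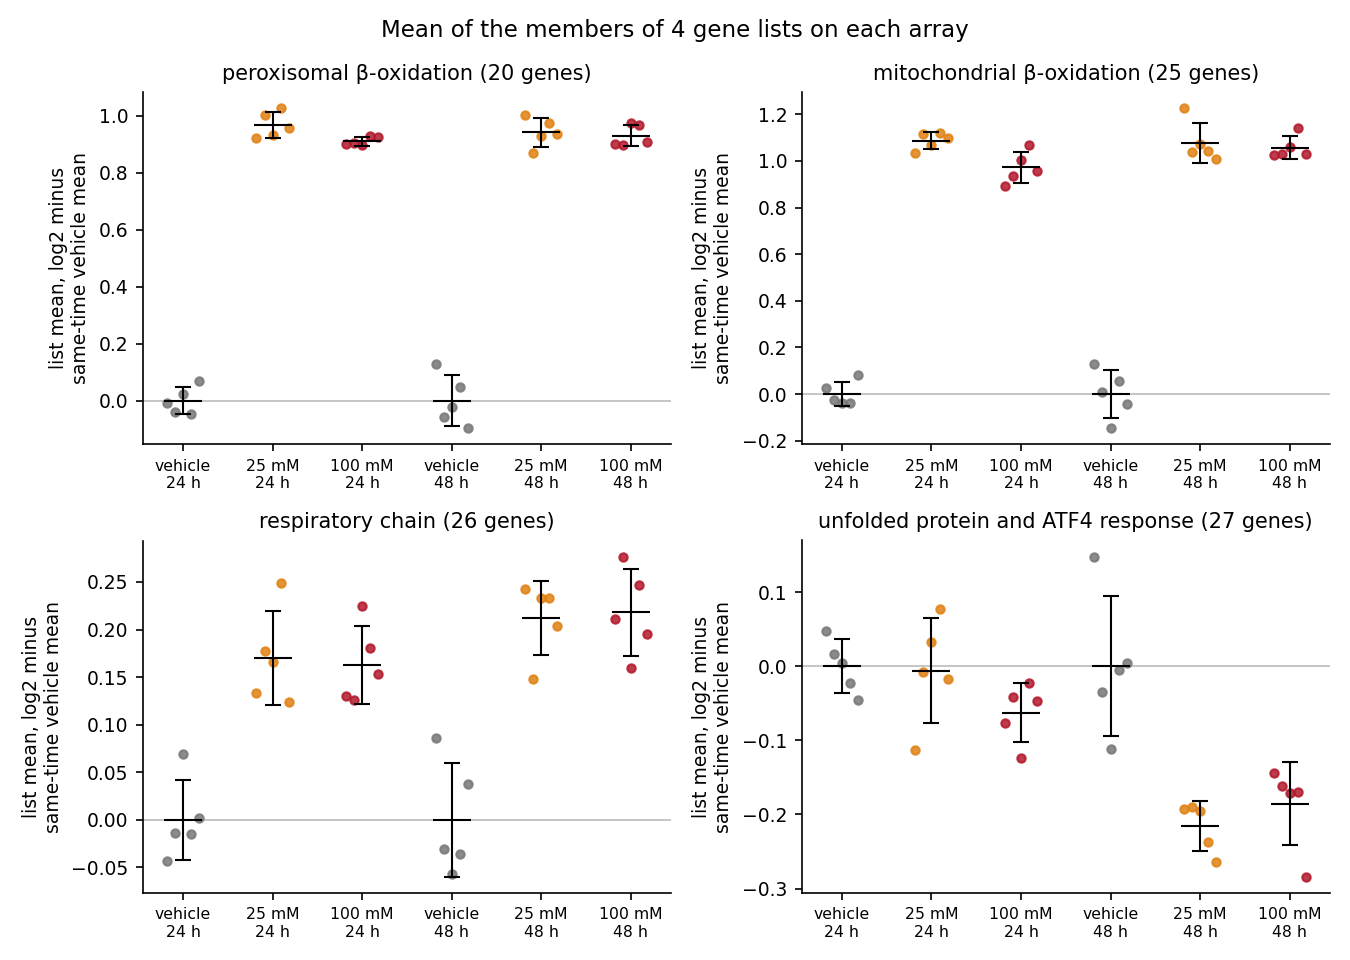
Mean log2(signal + 16) of the members of 4 gene lists on each array, minus the mean of the vehicle arrays of the same time, by group of dose (mM, as labelled) and time; points are arrays (5 per group), bars the group mean and error bars 1 SD. Means lay between 0.91 and 0.97 for the peroxisomal list and between 0.97 and 1.09 for the mitochondrial β-oxidation list in the 4 treated groups, while the unfolded protein and ATF4 list lay at -0.01 and -0.06 at 24 h and at -0.22 and -0.19 at 48 h.

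After 48 h at 25 mM, fatty acid genes were again among the most raised. Acot1 rose by at least 5.53 ± 0.35 (log2, adjusted p = 6.12e-14) and Ehhadh rose 7.01-fold (2.81 ± 0.10, adjusted p = 1.23e-19). Cyp4a1 rose 5.68-fold (2.50 ± 0.11, adjusted p = 1.01e-17) and Spc24 5.57-fold (2.48 ± 0.11, adjusted p = 2.42e-17). The kinase gene Nim1k rose by at least 3.04 ± 0.30 (adjusted p = 2.08e-09) and the fatty acid-binding protein Fabp3 by at least 2.27 ± 0.45 (adjusted p = 0.000335), from 48 h vehicle means of 5.90 and 6.95 (log2 signal), also below the dimmest mean tested. The calcium channel subunit Cacna2d3 rose by 2.21 ± 0.17, Acsl1 by 2.08 ± 0.09, Fabp1 by 2.06 ± 0.08 and Pdk4 by 2.04 ± 0.11. Cyp3a2, a P450 of drug and steroid oxidation, rose by 1.66 ± 0.14 (adjusted p = 6.73e-11). Ccn2 fell by 2.48 ± 0.10 (adjusted p = 2.15e-19) and the decoy interleukin-1 receptor Il1r2 by 2.42 ± 0.20 (adjusted p = 2.62e-11). Sned1 fell by 1.84 ± 0.39, Steap4 by 1.77 ± 0.13, Prr15l by 1.69 ± 0.46, Popdc2 by 1.49 ± 0.25 and Tcaf1 by 1.41 ± 0.36. Pmepa1 fell by 1.46 ± 0.43 (adjusted p = 0.0152), but without DINP 25 mM 48 h replicate 5 it was at -0.794 (adjusted p = 0.0565), and with only the compared groups its adjusted p was 0.0966.

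At 25 mM and 48 h all 20 peroxisomal genes rose, also adjusted over the list alone (median 0.87, camera adjusted p = 9.68e-36, and adjusted p = 3.71e-06 with an estimated correlation). In the mitochondrial β-oxidation list 23 of 25 rose and 0 fell, 23 adjusted over the list alone (median 0.89, camera adjusted p = 1.59e-42, and adjusted p = 1.32e-05 with an estimated correlation). Of the 28 uptake and droplet genes 17 rose and 2 fell, 20 and 2 adjusted over the list alone (median 0.48, camera adjusted p = 1.01e-14, and adjusted p = 3.87e-05 with an estimated correlation). Of the 8 ω-hydroxylation genes 4 rose and 0 fell, 4 adjusted over the list alone (median 0.14, camera adjusted p = 0.000548, but adjusted p = 0.085 with an estimated correlation). The respiratory chain list had 19 members higher and 0 lower, 23 higher and 1 lower adjusted over the list alone (median 0.21, camera adjusted p = 6.81e-11, but adjusted p = 0.0603 with an estimated correlation and 0.0408 without vehicle 48 h replicate 1). Median centring called 11 of them. Of the 16 glucose genes 8 rose and 3 fell, 8 and 3 adjusted over the list alone (median 0.14, camera adjusted p = 0.000909, but adjusted p = 0.085 with an estimated correlation). Fatty acid and triglyceride synthesis had 8 higher and 10 lower, 9 and 10 adjusted over the list alone (camera adjusted p = 0.869).

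Of the stress lists, that of unfolded proteins and ATF4 and that of p53 ran lower at 25 mM and 48 h, and those of NRF2 and heat shock were not called (camera adjusted p = 0.461 each). Of 27 genes of the unfolded protein and ATF4 response, 11 fell and 0 rose, 12 adjusted over the list alone (median -0.17, camera adjusted p = 0.00121, but adjusted p = 0.085 with an estimated correlation). The stress-induced regulator Nupr1 fell by 0.66 ± 0.06, the endoplasmic reticulum chaperone Hsp90b1 by 0.63 ± 0.07 and the folate enzyme Mthfd2 by 0.68 ± 0.17. On vehicle 48 h replicate 1, the array that stood apart from its group on the most probe sets, Hsp90b1 lay at 14.67 (log2 signal), below 14.99 to 15.12 on the other 4. Without this array 9 members fell (camera adjusted p = 0.00457, but adjusted p = 0.137 with an estimated correlation). Of 17 genes of the p53 and DNA damage response 6 fell and 1 rose, 8 and 1 adjusted over the list alone (median -0.15, camera adjusted p = 0.0127, and adjusted p = 0.0473 with an estimated correlation), with Sesn1 lower by 0.84 ± 0.11.

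The CAR and PXR lists ran higher at 25 mM and 48 h. Of 15 genes responsive to the xenobiotic receptor CAR 7 rose and 1 fell, the same adjusted over the list alone (median 0.14, camera adjusted p = 0.00016, but adjusted p = 0.0636 with an estimated correlation and 0.0163 without vehicle 48 h replicate 1). Its member Ces2c, a carboxylesterase, rose by 0.87 ± 0.06, and outside the list the glutathione transferase Gstt3 rose by 1.14 ± 0.10. Of 7 genes responsive to the receptor PXR 3 rose and 0 fell, 3 adjusted over the list alone (median 0.25, camera adjusted p = 0.00391, but adjusted p = 0.085 with an estimated correlation). Of these, Cyp3a23-3a1 rose by 0.27 ± 0.05. Of 21 genes of cholesterol biosynthesis and uptake 8 fell and 1 rose, 10 and 1 adjusted over the list alone (median -0.17, camera adjusted p = 0.00342, but adjusted p = 0.302 with an estimated correlation), and 5 fell without vehicle 48 h replicate 1. The squalene epoxidase Sqle fell by 0.81 ± 0.11. Of 17 bile acid genes 8 rose and 3 fell, 9 and 5 adjusted over the list alone (median 0.23, camera adjusted p = 0.0224, but adjusted p = 0.302 with an estimated correlation and 0.0666 after quantile normalisation). The sterol transporter Abcg5 and the bile acid hydroxylase Cyp8b1 rose by 1.10 ± 0.13 and 0.94 ± 0.08, and outside the list Abcc2 fell by 0.90 ± 0.07.

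Liver-typical genes were also changed at 25 mM and 48 h. Of 30 genes of amino acid catabolism and the urea cycle 15 rose and 6 fell, 16 and 6 adjusted over the list alone (median 0.17, camera adjusted p = 0.00452, but adjusted p = 0.262 with an estimated correlation and 0.052 after quantile normalisation), with the histidine-degrading Uroc1 up by 1.11 ± 0.10 and Tat down (-0.82 ± 0.09). Of 21 secreted liver proteins and apolipoproteins 8 rose and 2 fell, 8 and 2 adjusted over the list alone (median 0.07, camera adjusted p = 0.00309, but adjusted p = 0.302 with an estimated correlation and 0.248 after quantile normalisation). The vitamin E-binding Afm rose by 1.01 ± 0.07 and the transcription factor Cebpa by 0.70 ± 0.09, and the protease inhibitor A2m fell by 0.72 ± 0.08 and the male-typical P450 Cyp2c11 by 1.12 ± 0.13. Ccnd1 rose by 0.44 ± 0.13 (adjusted p = 0.0174), a call lost without vehicle 48 h replicate 2 (0.397, adjusted p = 0.0521). Cyp7a1 fell by 0.52 ± 0.17 (adjusted p = 0.034). Leaving out DINP 25 mM 48 h replicate 1 (-0.434), 2 (-0.470) or 3 (-0.520), or vehicle 48 h replicate 1 (-0.486), 3 (-0.485) or 4 (-0.502), ended this call, as did quantile normalisation (adjusted p = 0.0618) and testing without a filter (0.0559). Cd36 (0.38 ± 0.14, adjusted p = 0.0664) did not pass the threshold. It did without DINP 25 mM 48 h replicate 2 (0.440, adjusted p = 0.0398) or vehicle 48 h replicate 1 (0.430, adjusted p = 0.0452), and also with quantile normalisation, the stricter filter, the round as a block and only the compared groups. Alb (0.15 ± 0.10) and Fgf21 (0.04 ± 0.20) did not pass it either. On vehicle 48 h replicate 1 Fgf21 lay at 11.68 (log2 signal), above 9.842 to 10.21 on the other 4, and leaving out 1 array gave -0.095 to 0.364, the highest without that array (adjusted p = 0.05). Cyp1a1 was at -0.11 ± 0.11, but at -0.315 (adjusted p = 1.75e-05) without vehicle 48 h replicate 1.

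At 25 mM and 48 h, 1380 probe sets were higher and 1953 lower, 17.9% of those tested, with 133 raised and 81 lowered at least 2-fold. These were 1037 genes higher and 1286 lower. The share that was higher was 41.4%, against 40.6% after median centring and 46.4% after quantile normalisation. The 5S rRNA control lay at 1845 ± 215 signal units (SD, n = 5) against 847.4 ± 98.6 in the 48 h vehicle (exact permutation test, 2-sided p = 0.0079, adjusted 0.032). The poly-A spikes were 0.327 log2 units brighter (exact permutation test, adjusted p = 0.032, n = 5). The mean r of these arrays with their own group was 0.9523, against 0.9548 in the vehicle, with no p-value given since a group's values share array pairs.

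After 48 h at 100 mM, Acot1 rose by at least 5.06 ± 0.35 (log2, adjusted p = 6.28e-13) and Nim1k by at least 2.59 ± 0.30 (adjusted p = 6.95e-08). Ehhadh rose 6.27-fold (2.65 ± 0.10, adjusted p = 6.64e-19), Cyp4a1 5.21-fold (2.38 ± 0.11, adjusted p = 4.17e-17) and Spc24 4.74-fold (2.25 ± 0.11, adjusted p = 3.61e-16). Pdk4 rose by 2.04 ± 0.11, Fabp3 by at least 2.00 ± 0.45, Fabp1 by 1.97 ± 0.08, Cacna2d3 by 1.96 ± 0.17, Acsl1 by 1.95 ± 0.09 and Cyp3a2 by 1.34 ± 0.14. Ccn2 fell by 2.21 ± 0.10, Il1r2 by 2.13 ± 0.20, Steap4 by 1.61 ± 0.13, the lens crystallin gene Cryaa by 1.59 ± 0.37 and the lipase Abhd2 by 1.50 ± 0.11. The AMP deaminase Ampd3 fell by 1.37 ± 0.17 and Acmsd by 1.34 ± 0.17. Prr15l fell by 1.52 ± 0.46 (adjusted p = 0.0217), a call lost without DINP 100 mM 48 h replicate 3 (-1.297, adjusted p = 0.0722) or vehicle 48 h replicate 4 (-1.421, adjusted p = 0.0561). Angptl4 rose by 1.49 ± 0.09, Vnn1 by 1.16 ± 0.07 and Cpt1a by 0.97 ± 0.14, and Cyp7a1 fell by 0.76 ± 0.17.

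Of the 20 peroxisomal genes, 20 rose at 100 mM and 48 h, also adjusted over the list alone (median 0.87, camera adjusted p = 5.93e-41, and adjusted p = 1.11e-06 with an estimated correlation). In the mitochondrial β-oxidation list 24 of 25 rose and 0 fell, 24 adjusted over the list alone (median 0.87, camera adjusted p = 1.11e-49, and adjusted p = 3.69e-06 with an estimated correlation). Of the 28 uptake and droplet genes 20 rose and 2 fell, 20 and 3 adjusted over the list alone (median 0.53, camera adjusted p = 1.38e-17, and adjusted p = 9.54e-06 with an estimated correlation). The respiratory chain list had 23 of 26 members higher and 0 lower, 23 adjusted over the list alone (median 0.23, camera adjusted p = 6.32e-14, and adjusted p = 0.0303 with an estimated correlation). Quantile normalisation called 13 of them. Of the 8 ω-hydroxylation genes 3 rose and 1 fell, 3 and 1 adjusted over the list alone (median 0.00, camera adjusted p = 0.0268, but adjusted p = 0.27 with an estimated correlation and 0.0763 after quantile normalisation). Of the 16 glucose genes 7 rose and 3 fell, 7 and 3 adjusted over the list alone (median 0.14, camera adjusted p = 0.000662, but adjusted p = 0.1 with an estimated correlation). Fatty acid and triglyceride synthesis had 4 higher and 9 lower, 9 and 9 adjusted over the list alone (camera adjusted p = 0.826), but 8 and 7 without vehicle 48 h replicate 1 (0.55).

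In the unfolded protein and ATF4 list 9 of 27 fell at 100 mM and 48 h and 0 rose, 11 fell adjusted over the list alone (median -0.17, camera adjusted p = 0.0144, but adjusted p = 0.221 with an estimated correlation). Median centring left 3 of these calls, and without vehicle 48 h replicate 1 it was 4 (camera adjusted p = 0.0446, but adjusted p = 0.298 with an estimated correlation). Nupr1 fell by 0.51 ± 0.06 and Hsp90b1 by 0.43 ± 0.07. Of the 17 p53 genes 6 fell and 1 rose, the same adjusted over the list alone (median -0.12, camera adjusted p = 0.0388, but adjusted p = 0.0819 with an estimated correlation). Of the 15 CAR genes 4 rose and 1 fell, 8 and 1 adjusted over the list alone (median 0.15, camera adjusted p = 0.000284, but adjusted p = 0.0819 with an estimated correlation). Of them 6 rose and 0 fell without vehicle 48 h replicate 1 (adjusted p = 0.0173 with an estimated correlation). Ces2c rose by 0.87 ± 0.06. Of the 7 PXR genes 3 rose and 1 fell, 4 and 1 adjusted over the list alone (median 0.20, camera adjusted p = 0.0108, but adjusted p = 0.147 with an estimated correlation), with Cyp3a23-3a1 up by 0.34 ± 0.05.

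Of the 30 amino acid genes 13 rose and 6 fell at 100 mM and 48 h, 15 and 6 adjusted over the list alone (median 0.15, camera adjusted p = 0.0268, but adjusted p = 0.357 with an estimated correlation and 0.42 after quantile normalisation). Of the 21 secreted proteins 6 rose and 2 fell, 8 and 2 adjusted over the list alone (median 0.11, camera adjusted p = 0.000217, but adjusted p = 0.232 with an estimated correlation and 0.42 after quantile normalisation). Afm rose by 0.89 ± 0.07, Uroc1 by 0.79 ± 0.10 and Cebpa by 0.50 ± 0.09, while Cyp2c11 fell by 0.93 ± 0.13 and A2m by 0.63 ± 0.08. Cholesterol genes (2 higher, 2 lower; 2 and 4 adjusted over the list alone; camera adjusted p = 0.843) and bile acid genes (8 higher, 4 lower; 9 and 5 adjusted over the list alone; camera adjusted p = 0.0998) were not called as lists. Cd36 rose by 0.46 ± 0.14 (adjusted p = 0.0286), a call lost without DINP 100 mM 48 h replicate 3 (0.440), 4 (0.454) or 5 (0.351), or without vehicle 48 h replicate 2 (0.441), 3 (0.455), 4 (0.444) or 5 (0.431). Ccnd1 (0.36 ± 0.13, adjusted p = 0.0636) did not pass the threshold, but did without DINP 100 mM 48 h replicate 4 (0.467, adjusted p = 0.0157), after median centring (0.0174), after quantile normalisation (0.0179) and with the stricter filter (0.048). Alb (0.10 ± 0.10) and Fgf21 (0.04 ± 0.20, but 0.368 without vehicle 48 h replicate 1) did not pass it. Cyp1a1 was at -0.10 ± 0.11, and at -0.300 (adjusted p = 4.72e-05) without vehicle 48 h replicate 1.

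In all, 1208 probe sets were higher and 1503 lower at 100 mM and 48 h, 14.6% of those tested, with 85 raised and 63 lowered at least 2-fold. These were 921 genes higher and 976 lower. The share that was higher was 44.6%, against 75.1% after median centring, which moved the median of all probe sets from -0.074 to 0.030, and 51.7% after quantile normalisation. The 5S rRNA control lay at 1613 ± 335 signal units (SD, n = 5) against 847.4 ± 98.6 in the vehicle (exact permutation test, 2-sided p = 0.0079, adjusted 0.032). The poly-A spikes were 0.281 log2 units brighter (exact permutation test, adjusted p = 0.1, n = 5).

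**Figure D3:**
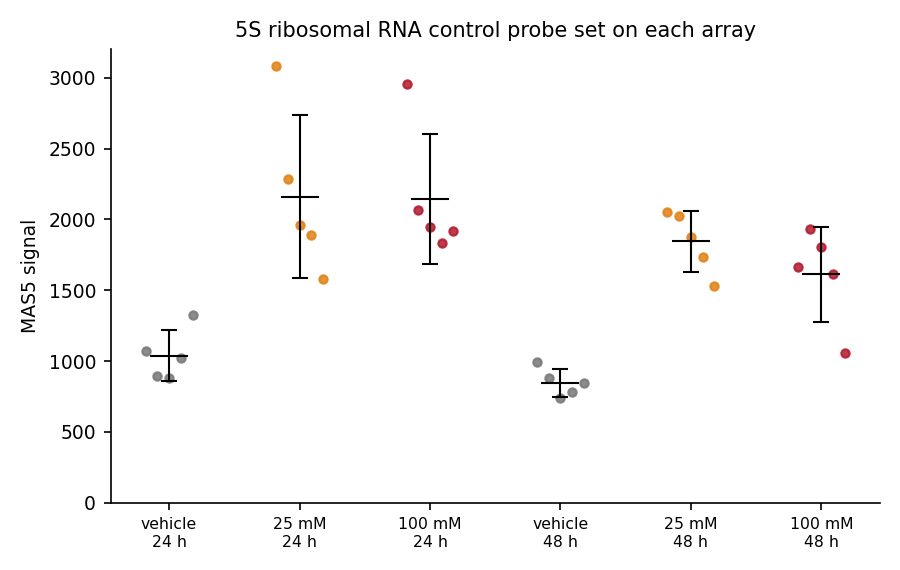
Signal of the 5S rRNA control probe set on each array (linear signal units) by group of dose (mM, as labelled) and time; points are arrays (5 per group), bars the group mean and error bars 1 SD. Vehicle arrays lay between 880.32 and 1323.80 at 24 h and between 736.27 and 992.48 at 48 h, and treated arrays between 1581.60 and 3083.50 at 24 h and between 1055.60 and 2048.80 at 48 h.

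The response at 100 mM was scarcely distinguishable from that at 25 mM. At 24 h limma called 2 probe sets higher at 100 than at 25 mM and 0 lower, with 764 at an unadjusted p under 0.05. The first was Ccn2, which fell less at 100 mM (difference 0.68 ± 0.10, adjusted p = 0.000839, but 0.117 with only the compared groups in the fit). The second was a dimmer probe set of Ddx54 (1.505 ± 0.223, adjusted p = 0.00125), named after its values were seen, whose brighter probe set was at -0.048 ± 0.154. At 48 h it called only Fam3c, a secreted protein gene (0.51 ± 0.08, adjusted p = 0.016), with 1403 probe sets at an unadjusted p under 0.05. Fam3c was lower at 25 mM (-0.84 ± 0.08) and at 100 mM (-0.32 ± 0.08) than in the vehicle. Its dose difference was lost without DINP 100 mM 48 h replicate 1 (0.483, adjusted p = 0.0647), 3 (0.518, adjusted p = 0.0562), 4 (0.508, adjusted p = 0.0777) or 5 (0.495, adjusted p = 0.102). It was also lost without a variance trend (adjusted p = 0.0757) and with only the compared groups (0.201), and 4 probe sets were called without DINP 25 mM 48 h replicate 4 and 2 without its replicate 5. The 95% interval of the dose difference, not adjusted for the number of tests, reached a median of 0.284 to either side over all probe sets. The simulations recovered 50% of dose differences of 0.5 at 24 h and 48% at 48 h, but with 123 and 133 probe sets called. The adjustment is stricter where fewer probe sets pass, as in the real dose comparisons, so these shares overstate the recovery there. Differences of that size or smaller could thus often go unseen, and larger ones may too. Among probe sets called at either dose, the interval lay within 1 log2 unit of 0 for 97.7% at 24 h and 96.6% at 48 h.

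Both doses changed many probe sets in the same direction. At 24 h 856 were higher and 923 lower at both doses and 0 went opposite ways, where independent lists of these sizes would share 60.5 and 94. With all arrays, the shared vehicle included, simulated as independent noise without an effect, the doses shared 0 calls. Such noise gives few calls by construction, so this says little about the real vehicle arrays. The log2 differences of both doses correlated across probe sets at r = 0.792 against 0.5 in simulations without an effect, with a covariance of 0.0704 against 0.02, so that the difference of 0.0505 estimates what the doses share beyond the vehicle arrays. With the vehicle arrays split between the doses, 444 to 503 were higher and 325 to 428 lower at both, over 20 allocations. At 48 h 1017 were higher and 1108 lower at both doses and 0 opposite (89.5 and 158 for independent lists), with r = 0.767 against 0.503 and a covariance of 0.0757 against 0.0201, a difference of 0.0556. With the vehicle split, 568 to 659 were higher and 424 to 536 lower at both. Probe sets are not independent replicates. Among probe sets called at either dose, 61.2% at 24 h and 64.7% at 48 h had the smaller change at 100 mM.

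**Figure D4:**
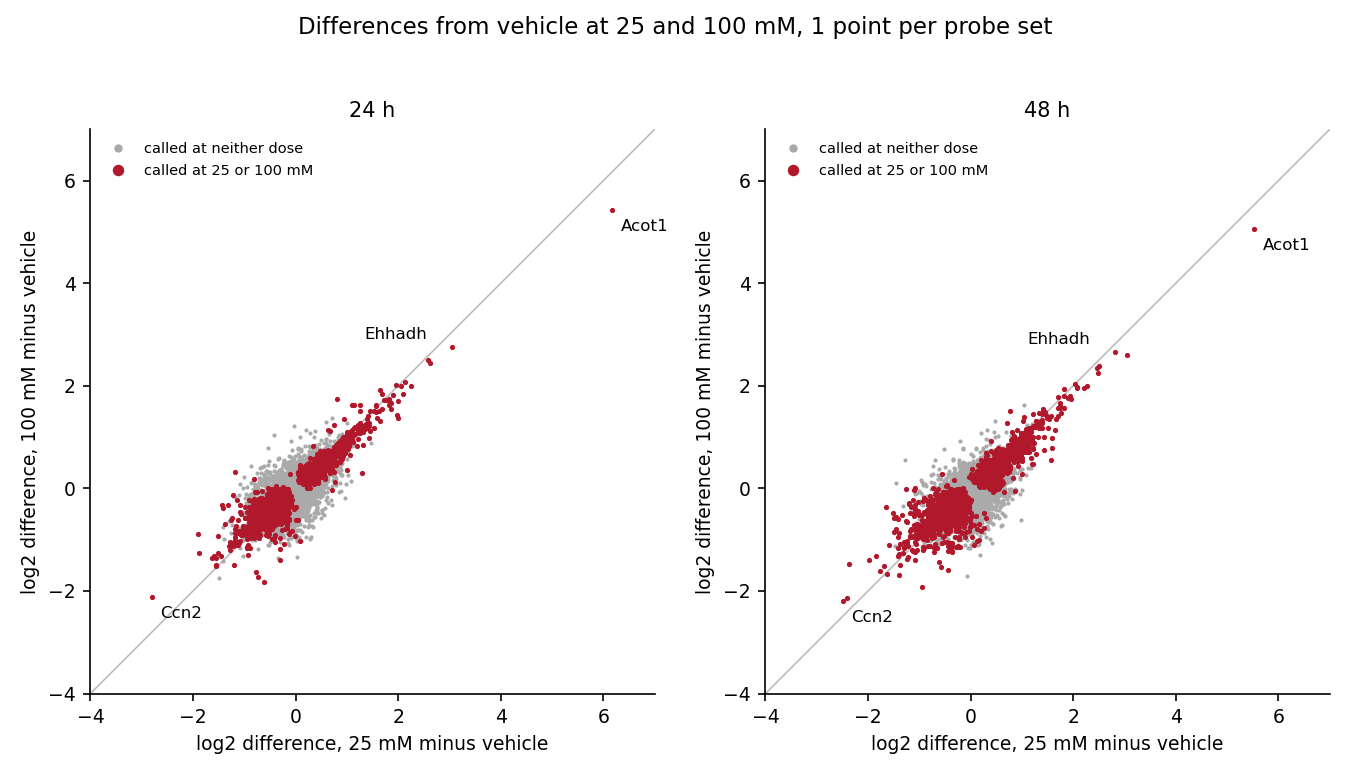
Log2 difference from the vehicle at 100 mM (vertical axis) against that at 25 mM (horizontal axis), with 1 point per tested probe set, at 24 h and at 48 h; red points are called at either dose and the grey line marks equal change. Called points lie along the line (2984 of 2994 have the same sign at both doses at 24 h, and 3889 of 3919 at 48 h), with Acot1 and Ehhadh at the upper end and Ccn2 at the lower.

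Between the doses the lists moved little. Cholesterol genes stood higher at 100 than at 25 mM at 48 h, with a median of 0.15 and 10 of 21 higher adjusted over the list alone but 0 over all genes (camera adjusted p = 9.75e-11, but adjusted p = 0.119 with an estimated correlation). At 24 h their median was 0.10 with 0 called either way (camera adjusted p = 5.64e-06, but adjusted p = 0.42 with an estimated correlation), and Sqle, for example, was at -0.56 ± 0.11 at 25 mM and -0.46 ± 0.11 at 100 mM against the vehicle. At 24 h the peroxisomal list lay slightly lower at 100 mM (median -0.05, camera adjusted p = 0.00876, but adjusted p = 0.423 with an estimated correlation). So did the mitochondrial β-oxidation list (-0.07, camera adjusted p = 0.00032, but adjusted p = 0.423 with an estimated correlation) and the interferon list (-0.14, camera adjusted p = 5.64e-06, but adjusted p = 0.213 with an estimated correlation). In the peroxisomal and β-oxidation lists 0 members passed the threshold between the doses over all genes, and 2 interferon genes were lower adjusted over the list alone. At 48 h the ω-hydroxylation list was lower at 100 mM (median -0.16, 2 lower adjusted over the list alone, camera adjusted p = 0.0107, but adjusted p = 0.415 with an estimated correlation). Median centring moved the median of all probe sets in this 48 h dose comparison from -0.016 to 0.089.

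Part of the response differed between 24 and 48 h. Cyp3a2 was not called at 24 h (0.29 ± 0.14 at 25 mM and -0.19 ± 0.14 at 100 mM) and rose at 48 h. The time difference was 1.37 ± 0.20 at 25 mM and 1.54 ± 0.20 at 100 mM (adjusted p = 6e-04 and 8.66e-05). Over time Cyp3a2 fell by 1.51 ± 0.14 in the vehicle. Fabp1 rose more at 48 h, by 0.64 ± 0.11 and 0.70 ± 0.11 (adjusted p = 0.0027 and 0.00311, but 0.1 at 25 mM after median centring). The ketone body enzyme Bdh1 differed by 0.90 ± 0.14 and 0.80 ± 0.14 (adjusted p = 0.00112 and 0.00845) and Afm by 0.77 ± 0.09 and 0.85 ± 0.09 (adjusted p = 6.23e-05 and 5.42e-06), but both fell over time in the vehicle. Ces2c differed by 0.51 ± 0.09 and 0.49 ± 0.09 (adjusted p = 0.00263 and 0.0117, but 0.056 at 25 mM after median centring and 0.0747 at 100 mM without a variance trend). Il1r2 fell further at 48 h, with differences of -1.74 ± 0.28 and -1.59 ± 0.28 (adjusted p = 0.00112 and 0.00831), as did the calcium-binding S100a6, with -1.0 ± 0.16 and -0.91 ± 0.16 (adjusted p = 0.00112 and 0.00831).

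At 25 mM the time difference was also called for Dhrs7l1 (0.92 ± 0.18, adjusted p = 0.00898, but 0.0933 after median centring), Gstt3 (0.80 ± 0.14, adjusted p = 0.00254), Cryab (-0.70 ± 0.13, adjusted p = 0.00664), A2m (-0.63 ± 0.12, adjusted p = 0.0072) and Nupr1 (-0.52 ± 0.09, adjusted p = 0.0025). Nim1k, with log2 rises of 1.21 ± 0.30 at 24 h and 3.04 ± 0.30 at 48 h at this dose, did not reach the threshold for the difference (1.83 ± 0.42, adjusted p = 0.0592), which rests on vehicle means below the dimmest mean tested. The lymphocyte-antigen family gene Ly6i rose more at 48 h at both doses (0.70 ± 0.11, adjusted p = 0.000943, and 0.56 ± 0.11, adjusted p = 0.0186). At 100 mM this call was lost without DINP 100 mM 48 h replicate 1 (0.526, adjusted p = 0.0542), DINP 100 mM 24 h replicate 2 (0.536, adjusted p = 0.0532) or vehicle 24 h replicate 3 (0.532, adjusted p = 0.0534). In all, the time difference was called for 30 probe sets upwards and 15 downwards at 25 mM, with 1527 at an unadjusted p under 0.05, and 6 and 7 were called after median centring. At 100 mM it was called for 9 upwards and 3 downwards, with 1165 at an unadjusted p under 0.05. The 12 calls at 100 mM became 21 without vehicle 48 h replicate 1 and 20 without vehicle 24 h replicate 2. They became 24 after quantile normalisation and 25 with array weights.

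**Figure D5:**
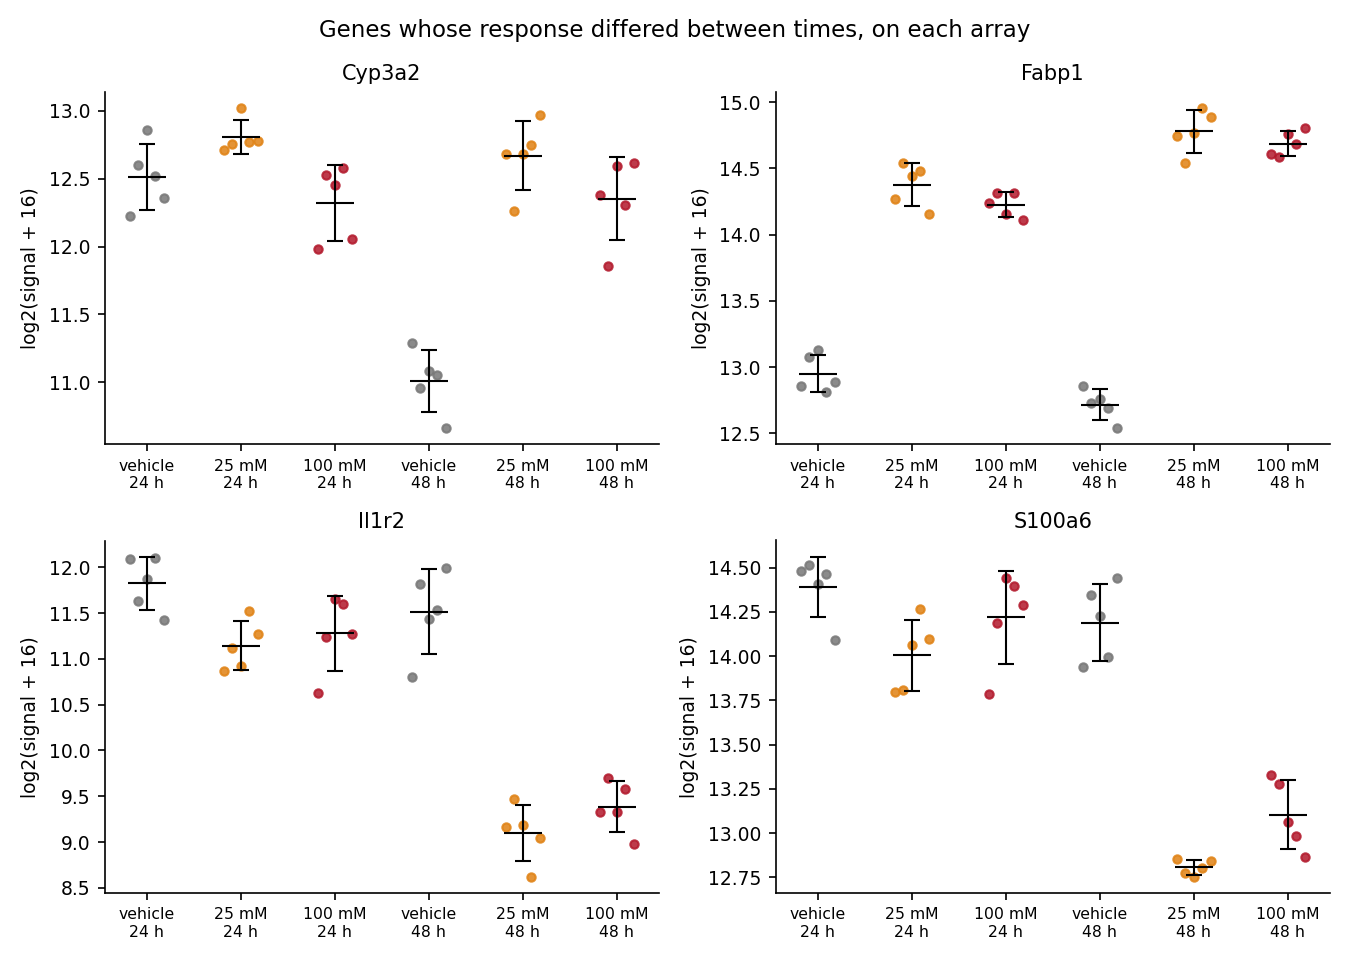
Signal of Cyp3a2, Fabp1, Il1r2 and S100a6 on each array, as log2(signal + 16), in the 6 groups of dose (mM, as labelled) and time; points are arrays (5 per group), bars the group mean and error bars 1 SD. Group means of Cyp3a2 were 12.51, 12.81 and 12.32 at 24 h and 11.01, 12.67 and 12.35 at 48 h for vehicle, 25 and 100 mM, and those of Il1r2 were 11.82, 11.14 and 11.28, then 11.52, 9.10 and 9.39.

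Of the lists, only the PXR genes had a time difference called with an estimated correlation at both doses, with a median of 0.14 at 25 mM (1 of 7 higher, 3 adjusted over the list alone; camera adjusted p = 8.91e-06, and adjusted p = 0.0334 with an estimated correlation). At 100 mM the median was 0.26 (1 higher, 4 adjusted over the list alone; camera adjusted p = 1.62e-07, and adjusted p = 0.00804 with an estimated correlation). Cyp3a2 was the PXR gene past the threshold over all genes at both doses. The unfolded protein and ATF4 list was lower at 48 h than at 24 h at 25 mM (median -0.17, 1 lower, 4 adjusted over the list alone; camera adjusted p = 8.91e-06, and adjusted p = 0.0334 with an estimated correlation). The CAR list was higher at 25 mM (median 0.12, 3 higher, 5 higher and 1 lower adjusted over the list alone; camera adjusted p = 4.1e-05, but adjusted p = 0.0692 with an estimated correlation). It was also higher at 100 mM (median 0.08, 1 higher, 3 adjusted over the list alone; camera adjusted p = 0.000531, but adjusted p = 0.213 with an estimated correlation). Without vehicle 48 h replicate 1 these CAR values were 0.0119 and 0.0099 with an estimated correlation.

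In the vehicle cultures, the largest falls between 24 and 48 h included genes of secreted liver proteins and P450 enzymes. The largest was that of Serpina6, the corticosteroid-binding globulin, at 6.21-fold lower (-2.64 ± 0.14, adjusted p = 5.62e-15), followed by Cyp2c13, a male-typical P450 (-2.29 ± 0.14, adjusted p = 1.66e-13), the secreted protease inhibitor Serpina3c (-2.12 ± 0.14, adjusted p = 1.99e-12) and Gstp3 (-2.08 ± 0.34, adjusted p = 6.33e-05). Nim1k was called lower (-1.60 ± 0.30, adjusted p = 0.000332, but 0.0855 with only the compared groups), but both vehicle means (7.49 and 5.90) lay below the dimmest mean tested, so no measured fall is shown. Tgfb2, a growth factor gene, rose by 2.11 ± 0.44 (adjusted p = 0.00114) and Lad1 by 1.86 ± 0.41 (adjusted p = 0.00191). The actin gene Acta1 rose by 1.72 ± 0.19 (adjusted p = 6.95e-08), the fatty acid desaturase Scd2 by 1.68 ± 0.13 (adjusted p = 2.08e-11) and Tsx by 1.56 ± 0.16 (adjusted p = 2.98e-08). Afm fell by 1.33 ± 0.07 and Bdh1 by 0.58 ± 0.10. Some genes that DINP raised also rose over time in the vehicle, among them Cd36 (1.15 ± 0.14), Aldh1a1 (0.73 ± 0.07), Cyp4a1 (0.72 ± 0.11), Vnn1 (0.69 ± 0.07) and Ehhadh (0.54 ± 0.10).

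By list, cholesterol genes were higher in the vehicle at 48 h (12 of 21 higher and 1 lower, 15 and 1 adjusted over the list alone, median 0.25, camera adjusted p = 6.71e-06). Fatty acid synthesis genes were higher too (11 and 1, with 12 and 2 adjusted over the list alone, 0.21, camera adjusted p = 0.00218), with 7 and 1 without vehicle 48 h replicate 1 (0.00344). So were uptake and droplet genes (12 and 2, both ways of adjusting, 0.21, camera adjusted p = 0.00031) and CAR genes (9 and 3, both ways of adjusting, 0.34, camera adjusted p = 0.00457). Acute phase and complement genes were lower (11 of 26 lower and 2 higher, 14 and 2 adjusted over the list alone, -0.15, camera adjusted p = 1.12e-06), as were interferon genes (6 of 18 lower, 8 adjusted over the list alone, -0.11, camera adjusted p = 0.000558). PXR genes (3 of 7 lower, -0.28, camera adjusted p = 0.00484) and constitutive P450 genes (5 of 19 lower, with 5 lower and 1 higher adjusted over the list alone, -0.07, camera adjusted p = 0.00561) also ran lower. Secreted proteins were called lower (9 of 21 lower and 0 higher, camera adjusted p = 3.03e-05) with a mean of -0.22 and a median of 0.00. None of these calls held with an estimated correlation, where the lowest adjusted p was 0.125. Amino acid genes (3 of 30 higher and 5 lower, camera adjusted p = 0.703) and bile acid genes (3 of 17 higher and 2 lower, camera adjusted p = 0.685) were not called. The liver transcription factor (3 of 15 lower, camera adjusted p = 0.0477) and heat shock lists (5 of 13 higher and 1 lower, 7 and 1 adjusted over the list alone, camera adjusted p = 0.0234) lost their calls without vehicle 48 h replicate 1 (0.0824 and 0.0723). In all, 1243 probe sets were higher and 1431 lower, for 1006 genes higher and 840 lower, with 33 raised and 44 lowered at least 2-fold.

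Markers of other liver cell types were measured alongside. Of 11 stellate cell and fibroblast markers 0, 1, 1 and 0 rose and 2, 2, 2 and 3 fell at 25 and 100 mM at 24 h and at 25 and 100 mM at 48 h (camera adjusted p = 0.316, 0.254, 0.275 and 0.273). Vim and the collagen cross-linking enzyme Lox fell in all 4 comparisons, Vim by between 0.79 ± 0.11 and 1.09 ± 0.11 and Lox by between 0.68 ± 0.17 and 0.96 ± 0.17, beside the fall of Ccn2. On vehicle 48 h replicate 1 Lox lay at 13.32 (log2 signal), below 14.38 to 14.65 on the other 4. Of 14 Kupffer cell and macrophage markers 2, 1, 2 and 2 rose and 1, 0, 1 and 0 fell. Of these, Cd14 rose in all 4, by 0.19 ± 0.05 at the least, at 100 mM and 24 h, where quantile normalisation ended the call (0.110, adjusted p = 0.11). The complement gene C1qb rose at 48 h by 0.79 ± 0.24 and 0.94 ± 0.24. At 25 mM it lost its call without DINP 25 mM 48 h replicate 3 (0.693, adjusted p = 0.0561) or vehicle 48 h replicate 3 (0.676, adjusted p = 0.0576) and with only the compared groups (0.0796). Of 5 cholangiocyte and progenitor markers 1, 0, 0 and 0 rose and 1, 1, 2 and 2 fell, with Prom1 lower by between 0.61 ± 0.16 and 0.88 ± 0.16. Of 6 endothelial markers 0 changed under limma in any of the 4. Of 2 lymphocyte markers 1, 1, 0 and 0 rose, and of 3 erythroid markers 1 rose, at 100 mM and 24 h. No marker list was called by camera against the vehicle.

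The remaining lists were not called by camera against the vehicle. Their counts are given in the order 25 and 100 mM at 24 h, then 25 and 100 mM at 48 h, beside 1666, 1544, 2323 and 1897 of all 10604 genes called. Of 22 genes of the NRF2 oxidative stress response 3, 3, 5 and 5 rose and 4, 4, 3 and 3 fell. Of 9 AhR-responsive genes 0, 0, 1 and 0 rose and 1, 0, 1 and 2 fell. Of 18 cell cycle and DNA replication genes 2, 1, 2 and 0 rose and 1, 0, 0 and 0 fell. Of 13 heat shock genes 2, 3, 1 and 1 rose and 0, 0, 2 and 0 fell. Of 7 metallothionein and metal handling genes 0 rose and 2, 2, 2 and 1 fell. Inflammatory and NF-κB genes (13 measured) had 0, 1, 1 and 2 higher and 2, 1, 3 and 3 lower, the last pair becoming 1 and 1 without vehicle 48 h replicate 1. Interferon genes (18 measured) had 0, 1, 1 and 1 higher and 0, 1, 4 and 3 lower. Acute phase and complement genes (26 measured) had 2, 1, 4 and 4 higher and 2, 4, 6 and 8 lower (camera adjusted p = 0.729, 0.273, 0.495 and 0.779). Quantile normalisation gave 0, 0, 4 and 4 higher and 5, 6, 12 and 12 lower, with camera adjusted p = 0.0499, 0.00153, 0.023 and 0.00305. Of 19 constitutive and sex-biased P450 and steroid genes 1, 1, 5 and 4 rose and 4, 2, 3 and 4 fell, and of 15 liver transcription factors 3, 3, 6 and 4 rose and 3, 1, 1 and 1 fell.

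At 24 h the lists called at 48 h for stress, drug metabolism, sterols and liver-typical genes were not called, at 25 and then 100 mM. Unfolded protein and ATF4 genes had 1 and 0 higher and 2 and 2 lower (camera adjusted p = 0.87 and 0.361), and p53 genes 1 and 2 higher and 5 and 4 lower (0.272 and 0.088). CAR genes had 4 and 3 higher and 2 and 1 lower (camera adjusted p = 0.237 and 0.181), and PXR genes 1 and 0 higher and 1 and 1 lower (0.97 and 0.476). Cholesterol genes had 1 and 1 higher and 4 and 2 lower (camera adjusted p = 0.194 and 0.854), and bile acid genes 5 and 5 higher and 4 and 5 lower (0.87 and 0.854). Amino acid genes had 9 and 7 higher and 6 and 6 lower (camera adjusted p = 0.729 and 0.854), and secreted proteins 2 and 1 higher and 1 and 1 lower (0.197 and 0.405).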

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

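The tests of an array ceiling, of mixed-up doses, of messenger RNA content and of array order, the shuffles of residuals and the list tests without 1 vehicle array were chosen after the results they concern had been seen.

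No further rise of the fatty acid genes from 25 to 100 mM was seen. Over the fatty acid list members that rose, the mean log2 difference, 100 minus 25 mM, was -0.062 ± 0.030 at 24 h (64 genes; exact permutation p = 0.071, 5 arrays against 5) and -0.019 ± 0.032 at 48 h (68 genes; exact permutation p = 0.56). A ceiling of the array signal would leave the dimmer members free to rise further, but these were at -0.059 ± 0.036 at 24 h, which argues against it, and at -0.038 ± 0.041 at 48 h, where a small further rise stays open. Arrays mixed at random between the doses are argued against only weakly at 24 h. There 1 of 100 splits, the real one, called as many probe sets. That rests on 2 calls, against at most 1 in the other splits, and only the compared groups in the fit left 0. The calls were Ccn2 (0.68 ± 0.10, limma adjusted p = 0.000839, but 0.117 with only the compared groups) and a dim Ddx54 probe set, whose brighter probe set was not called. At 48 h such mixing stays open (17 of 100). Exchanged whole groups or a few misplaced arrays were not tested and stay open at both times. A response already at its maximum at 25 mM was not tested, for lack of a lower dose.

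The 5S rRNA control, which no comparison uses, was brighter in the treated arrays by ratios of 2.08 and 2.07 at 24 h (25 and 100 mM) and 2.18 and 1.9 at 48 h. Less messenger RNA in the labelled total RNA would raise the poly-A spikes as much. The spikes rose by 0.13 ± 0.06 at 24 h and 0.30 ± 0.07 at 48 h (log2), and the 5S log2 rise exceeded theirs by 0.909 and 0.71. This argues against it as the whole of the 5S rise, if the spikes were added in proportion to total RNA, as the labels do not state. A part in the rise stays open. A steady drift over the array order is argued against, since the log2 step from the vehicle to the 25 mM array exceeded the next, from 25 to 100 mM, by 1.19 ± 0.15 (10 pairs of steps), and the 48 h vehicle array was below both earlier 24 h treated arrays of its round (10 of 10 pairs). An effect of the place within a round stays open: the treated array was higher in 20 of 20 pairs, but it also came after its vehicle array in all 20. No biological explanation was tested.

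Single arrays stood apart from the other 4 of their group (by over 0.71 of the group's range), and chance sets about 1 in 20 groups apart. This held for 2 of 42 array checks (chance 2.1), 12 of 186 list groups (9.3) and 36 of 588 gene groups (29.4). The array checks were the GAPDH 3' to 5' ratio (25 mM 48 h replicate 5, 0.764) and 5S (100 mM 24 h replicate 1, 0.795). The lists were mitochondrial β-oxidation (25 mM 48 h replicate 1, 0.712), fatty acid uptake and droplets (vehicle 24 h replicate 4, 0.721), NRF2 (25 mM 24 h replicate 4, 0.729), bile acid (vehicle 24 h replicate 5, 0.741), glucose (25 mM 24 h replicate 4, 0.796), amino acid (vehicle 24 h replicate 5, 0.841), amino acid (100 mM 24 h replicate 1, 0.784), constitutive P450 (25 mM 24 h replicate 5, 0.730), cell cycle (100 mM 48 h replicate 3, 0.809), unfolded protein and ATF4 (100 mM 48 h replicate 5, 0.806), cholangiocyte markers (25 mM 48 h replicate 3, 0.807) and lymphocyte markers (vehicle 24 h replicate 3, 0.885). The genes apart on vehicle 48 h replicate 1 (log2 signal) were Cyp1a1 (14.7 against 15.61 to 15.83, 0.806), Fgf21 (11.68 against 9.842 to 10.21, 0.797), Gpd1 (15.06 against 14.35 to 14.45, 0.860), Pfkfb3 (9.275 against 10.21 to 10.57, 0.721), Hsp90b1 (14.67 against 14.99 to 15.12, 0.714) and Lox (13.32 against 14.38 to 14.65, 0.796). That array had the lowest array weight, 0.518, and stood apart on 489 of 18625 probe sets. Other genes highest on 1 array were Acsl1 (vehicle 24 h replicate 5, 0.771), Cc2d2a (100 mM 24 h replicate 1, 0.737), B4galt5 (vehicle 24 h replicate 5, 0.813), Crat (100 mM 24 h replicate 4, 0.754), Tat (vehicle 24 h replicate 5, 0.712), Fabp3 (vehicle 48 h replicate 2, 0.881), Cyp3a2 (25 mM 24 h replicate 3, 0.778), Gpnmb (vehicle 48 h replicate 5, 0.754) and Serpina6 (25 mM 24 h replicate 3, 0.790). Genes lowest on 1 array were Cyp4a3 (25 mM 48 h replicate 2, 0.872), Ccn2 (vehicle 24 h replicate 3, 0.723), Sesn1 (100 mM 48 h replicate 3, 0.717), Hilpda (100 mM 48 h replicate 5, 0.781), Cyp1a1 (vehicle 24 h replicate 1, 0.785), Diaph3 (25 mM 24 h replicate 5, 0.766), Nim1k (100 mM 48 h replicate 4, 0.875), Cacna2d3 (25 mM 24 h replicate 5, 0.826), Prr15l (25 mM 48 h replicate 3, 0.735) and Pmepa1 (25 mM 48 h replicate 5, 0.827). Further such genes were Tcaf1 (100 mM 48 h replicate 5, 0.738), Abcg5 (vehicle 48 h replicate 4, 0.723), Uroc1 (100 mM 48 h replicate 5, 0.715), Ndufb8 (100 mM 24 h replicate 2, 0.749), Ndufb8 (vehicle 48 h replicate 4, 0.842), Cryaa (25 mM 24 h replicate 3, 0.814), Dhrs7l1 (100 mM 24 h replicate 3, 0.870), S100a6 (vehicle 24 h replicate 5, 0.750), Gpnmb (25 mM 48 h replicate 4, 0.783), Serpina6 (100 mM 24 h replicate 1, 0.750) and Serpina3c (100 mM 24 h replicate 1, 0.788).

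The effect differed between 48 and 24 h by limma's test of the difference for these genes. At 25 mM they were Fabp1 (0.64), Il1r2 (-1.74), Cyp3a2 (1.37), Ces2c (0.51), A2m (-0.63), Afm (0.77), Nupr1 (-0.52), Dhrs7l1 (0.92), Bdh1 (0.90), Slco1b2 (0.83), Gstt3 (0.80), S100a6 (-1.0), Cryab (-0.70), Gpnmb (-0.65), Ly6i (0.70) and Defb1 (-0.44). At 100 mM they were Fabp1 (0.70), Il1r2 (-1.59), Cyp3a2 (1.54), Ces2c (0.49), Afm (0.85), Bdh1 (0.80), S100a6 (-0.91), Ly6i (0.56) and Defb1 (-0.54). At 25 mM the calls of Defb1 (adjusted p = 0.0483), Slco1b2 and Gpnmb (0.0367 each) were lost under 6, 4 and 4 of 10 alternative settings and without any one of 13, 12 and 10 of the 20 arrays. Median centring also ended those of Fabp1 (0.1), Ces2c (0.056) and Dhrs7l1 (0.0933) at 25 mM and of Defb1 at 100 mM (0.0144 before, 0.183 after). Without a variance trend those of Ces2c and Defb1 at 100 mM were lost (0.0747 each), and that of Ly6i at 100 mM was lost without any one of 3 arrays. By camera the lists at 25 mM, as medians, were CAR (0.12), PXR (0.14), cholesterol (-0.10), bile acid (0.24), amino acid (0.09), secreted proteins (0.03, but -0.05 after median centring), constitutive P450 (0.28), liver transcription factors (0.16), unfolded protein and ATF4 (-0.17), heat shock (-0.11), interferon (-0.25) and respiratory chain (0.04, but -0.04 after median centring). At 100 mM they were mitochondrial β-oxidation (0.03), CAR (0.08), PXR (0.26), bile acid (-0.00, with a mean of 0.10), amino acid (0.08), secreted proteins (0.08), constitutive P450 (0.11), liver transcription factors (0.08), unfolded protein and ATF4 (-0.07), respiratory chain (0.07) and Kupffer markers (0.14). Several medians depended on vehicle 48 h replicate 1. Without it they were, at 100 mM, 0.09 for mitochondrial β-oxidation, 0.15 for CAR, 0.14 for bile acid and -0.02 for unfolded protein and ATF4. For heat shock at 25 mM the median was then -0.04. With an estimated correlation only PXR at both doses and unfolded protein and ATF4 at 25 mM kept their calls, and without vehicle 48 h replicate 1 so did CAR at both doses (0.0119 and 0.0099) and constitutive P450 at 25 mM (0.0455). At the preset correlation, leaving out that array ended the 25 mM calls of cholesterol (camera adjusted p = 0.079), liver transcription factors (0.0545) and heat shock (0.177). It also ended that of unfolded protein and ATF4 at 100 mM (0.099), where the peroxisomal list gained a call (0.0358).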

How the results depend on the processing

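Of the named genes' results under the alternatives, 7853 kept direction and call, 426 lost the call, 22 gained it and 12 reversed, all uncalled. Of the lists' results 1019 were the same, 106 lost the call (61 with an estimated correlation), 64 gained it (38 with fry) and 0 reversed. A threshold of 0.01, stricter by construction, left 1491 and 1283 probe sets at 24 h (25 and 100 mM), 2046 and 1639 at 48 h, 0 between doses at 48 h, 24 and 7 for the time difference (25 and 100 mM) and 1435 for vehicle time. A log2 difference of at least 1 left 150, 112, 214 and 148, then 1 and 0 between doses at 24 and 48 h, 2 and 2 for the time difference and 77 for vehicle time. Between doses at 24 h the filter at the 60th percentile gave 1 and only the compared groups 0; at 48 h no variance trend and only the compared groups gave 0, and the round as a block 2. What the rounds are is not stated in the labels, and they were compared only after the results were seen. Deviations of arrays from their group means correlated at a mean r of 0.0123 within rounds (-0.0611 to 0.0994) and -0.00308 across them. Of 30 arrays 12 correlated best with one of their own round, against 6.1 with the rounds shuffled, and 36 of 1000 shuffles gave as many and 19 as high a mean r. The block moved no other count by over 1.5 times, and of the named genes' results 7 lost the call with it and 1 gained it. For the time difference, median centring gave 13 at 25 mM, and quantile normalisation 24 and array weights 25 at 100 mM. Leaving out 1 array gave 1960 to 2443, 1712 to 2199, 2788 to 3453 and 2250 to 2825 probe sets against vehicle, 2 to 3 and 0 to 4 between doses, 31 to 57 and 10 to 21 for the time difference and 2022 to 2917 for vehicle time; with fewer arrays, fewer calls are expected by construction, and the cause of the rises was not tested. Reversed were Alb at 100 mM with quantile normalisation (-0.005 at 24 h, -0.021 at 48 h), Cyp1a1 at 100 mM and 48 h with median centring (0.009), and, without 1 array, Alb at 100 mM and 24 h (-0.034 to 0.100) and Fgf21 at 48 h (-0.095 to 0.364 at 25 mM, -0.091 to 0.368 at 100 mM); the cause was not tested. Signal over background could not be judged without detection calls.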

Other observations

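The tests of a smaller share of stellate cells and fibroblasts were chosen after the results they concern had been seen. Besides Ccn2, some genes of the actin cytoskeleton fell. Over both doses and times, limma called Flna (-0.67), Tpm4 (-0.50), Acta1 (-0.49), Acta2 (-0.37) and Actn1 (-0.31) lower, while Actg1 (0.04), Vcl (0.00), Myl9 (-0.12) and Tln1 (-0.25) did not pass the threshold. The transcription factor genes Junb (-0.42) and Egr1 (-0.37), the cofactor gene Fhl2 (-0.43) and the secreted Ccn1 (-0.65) were lower as well. Acta2 is also on the list of stellate cell and fibroblast markers, of which Vim (-0.79 to -1.09) and Lox (-0.68 to -0.96) were lower in all 4 comparisons. A smaller share of such cells would lower the list's other markers as far. Acta2 aside, 5 others lay at least 1 log2 unit above the dimmest mean tested, and their median log2 difference was 0.02 (-0.35 to 0.22, SD 0.22). This is 0.87 above the mean of Vim and Lox, over 2 SD, and 0.39 above Acta2, under 2 SD. Of the 5, limma called Col5a2 lower (-0.35, adjusted p = 0.00748) and Sparc higher (0.22, adjusted p = 0.0253). But their vehicle means, 9.07 to 10.04, lay far below those of Vim (13.63) and Lox (14.50). Signal over background could not be judged without detection calls, so the test cannot decide whether such cells were fewer. These genes were named after their values were seen.

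Because Ccn2 is a target of the regulators YAP/TAZ and SRF, 2 lists of their target genes were written before testing, although values of Acta2, Acta1 and Tgfb2 had been seen. Of 18 YAP/TAZ targets 7 fell and 1, Nuak2, rose (mean log2 difference -0.18), and of 20 SRF and actin genes 12 fell and 0 rose (mean -0.23). With an estimated correlation camera gave adjusted p = 0.0567 for each list, against 0.0627 and 7e-04 at the preset correlation, so the test cannot tell whether either activity was lower.

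A second hypothesis was that DINP at 48 h ran against the change of the vehicle cultures over time, as for Cyp3a2 and Afm. The genes' effects and time changes correlated at r = -0.132, but both share the 48 h vehicle arrays. With these arrays split, the mean covariance was 0.0051 (-0.00643 to 0.0162 over 20 allocations), and 0.00361 without the fatty acid lists. Over all genes the finding is negative, and single genes were not tested for it.

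Arrays were also split into other groups of 5, 100 times per comparison, counting the real one. Chance can be excluded at that resolution for 25 and 100 mM at 24 h (2485 and 2288 probe sets, highest other 413 and 230), at 48 h (3333 and 2711, against 1967 and 904) and for vehicle time (2674 against 509), where 1 of 100 splits, the real one, was as large. For dose at 24 h (2 against 1) the real split was again the only one as large, but that rests on 2 calls, of which only the compared groups in the fit left 0 and the filter at the 60th percentile 1, and the dim Ddx54 call was not shared by its brighter probe set (-0.048). Chance cannot be excluded for dose at 48 h (1 against 5, with 17 of 100 as large). For the time difference 5 of 100 splits were as large at 25 mM (45 against 1340) and 8 of 100 at 100 mM (12 against 3175). These splits cannot decide there, since mixing treated and vehicle arrays within a time turns the treatment effect into a time difference. Shuffles of residuals, chosen after the results were seen, keep the common effect. They gave at most 2 calls at either dose, with 0 of 100 as large as the real count, which argues against chance for the time difference.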
